A study of Caenorhabditis elegans with 25 samples.

How the data were processed

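Poly(A) RNA of whole day 1 adult C. elegans, 25 libraries from 5 genotypes with 5 replicates each, was measured by Illumina sequencing. Samples held 500 to 600 animals, and the mutant strains had been outcrossed 6 times, per the labels. The submitters aligned reads with STAR 2.7.11b to genome build ce11, per the submitters' processing notes. The deposited table holds raw counts per gene and library, per the labels and its whole-number values, without normalization. The counting program, its annotation and its strand setting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies in gene families, are of uncertain origin. Each library was matched to its sample by the sample name in the labels, and no library was left out.

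The table names 42532 genes by symbol. Positions came from the Ensembl 115 annotation of the same assembly, in which 40181 genes matched by symbol, 2260 more matched through RefSeq names and 91 stayed unmatched. Total counts per library ran from 25164923 to 99717657. The lowest chi-square per gene between replicates of a genotype was 5.67, so no replicate duplicated another of its genotype.

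Genes were kept by edgeR's filterByExpr by genotype (at least 10 counts scaled to library size in as many libraries as the smallest group, and 15 in total), which left 14634. Counts were scaled by TMM factors, and the median log2 change over all genes lay within 0.02 of 0 in every comparison. A single negative binomial model with a term for each genotype and a term for batch was fitted to all 25 libraries with edgeR 4.0.16 (robust quasi-likelihood) and limma 3.58.1 in R 4.3.3. From it came 5 comparisons of genotypes and the interaction of the array with egl-6(lof). Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison count as changed, with no minimum fold. Values in CPM use TMM-scaled library sizes, with SD over replicates.

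Of 39 lists of genes, 38 had the minimum of 3 tested members. Lists were tested with camera on log2 CPM (prior count 2) at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusting over the lists of a comparison. For each list, changed members were counted over all genes tested and adjusted over the list alone, and a score per library was formed as the mean log2 CPM of members minus each gene's mean over libraries. The genes flp-17 and egl-6 were left out of the lists.

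Named genes follow a fixed rule. They are flp-17, egl-6 and myo-3, and for each comparison the 8 largest rises and 8 largest falls among changed genes with a mean log2 CPM of at least 1 and all 5 libraries of one genotype on one side of the other's mean (for the interaction, the largest differences). From each list up to 4 changed members with the smallest p were added. The comparisons, the lists, the rule, the model and the alternatives were chosen before the data were examined.

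Deviations of same-numbered libraries from their genotype means, with batch not removed, correlated above 0.1 in all 5 pairs of flp-17oe and flp-17oe egl-6(lof), from 0.133 to 0.573. By this rule the replicate numbers were taken to pair these 2 genotypes, and no other 2. N2 and flp-17oe came close, from 0.0794 to 0.656, with replicate 3 alone under 0.1.

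Alternatives were DESeq2-type size factors within edgeR, DESeq2 1.42.0 with its own factors, no count filter, a stricter filter (10 counts in every library of a genotype), no batch term, a replicate block in place of batch, a fit to the compared genotypes alone, each replicate number left out in turn and each single library left out in turn. The test for changed genes near the mutated loci was also run with windows of 1 and 5 Mb in place of 2 Mb. For each comparison 50 splits of the libraries, the real one included, were refitted.

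The procedure was tested on simulated data with the depths of these libraries, the mean levels of N2 and the spread fitted over all 25 libraries, over 14255 genes. Genes were drawn independently and without a batch difference, and changes were placed in the egl-6(lof) libraries. It recovered 28% of 50 genes changed 1.25-fold, 57.1% of 49 changed 1.5-fold, 64.6% of 48 changed 2-fold and 96% of 50 changed 4-fold. Among its 155 calls 11 were unchanged genes, and a comparison without any change gave 1 call. A list of 60 genes shifted 1.3-fold had a camera p of 1.68e-48 and an unshifted list 0.271. As the simulated genes were independent, these values do not test the preset correlation.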

Results

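Poly(A) RNA was sequenced from whole C. elegans on day 1 of adulthood, with 500 to 600 animals per sample. The 25 libraries came from 5 genotypes with 5 replicates each. N2 was the wild type. The flp-17(lof) strain carried a loss-of-function allele of flp-17, which encodes FMRFamide-like neuropeptides of the BAG sensory neurons. The egl-6(lof) strain carried a loss-of-function allele of egl-6, which encodes the G protein-coupled receptor for FLP-17 on egg-laying neurons. The flp-17oe strain carried flp-17 on an extrachromosomal array, and flp-17oe egl-6(lof) carried such an array in the egl-6(lof) background. Replicate 1 of each genotype belonged to batch 1 and replicates 2 to 5 to batch 2. Array animals were sorted for a fluorescent marker 24 hours before collection while the other strains were washed and replated, so array and sorting coincide in every comparison of array with non-array animals.

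Total counts per library ran from 42696185 to 67059902 in N2, 25164923 to 99717657 in flp-17(lof), 48048407 to 76965846 in egl-6(lof), 42201172 to 64805969 in flp-17oe and 38300495 to 65575590 in flp-17oe egl-6(lof). One library stood apart: flp-17(lof) replicate 1 had 25164923 counts, with 9.5% of them from ribosomal RNA genes against 0.335% to 1.65% in the other libraries of its genotype, and a scaling factor of 0.740 against 0.981 to 1.01. After filtering, 14634 genes were tested. The first principal component held 39.7% of the variance. The labels do not say whether replicates came from separate cultures, so each p-value measures the spread between samples. For every gene given as among the largest rises or falls of a comparison, all 5 libraries of one genotype lay beyond the mean of the other. Such genes also had a mean log2 CPM of at least 1, and genes outside this rule could change by more.

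The manipulated genes differed between the strains in the directions the labels give. The flp-17 gene (WBGene00001460, ce11 chromosome IV, 17190204 to 17191891, minus strand) had 4.62 ± 0.459 CPM (counts scaled to library size, SD, n = 5) in N2, 0.310 ± 0.0607 in flp-17(lof), 4.64 ± 0.233 in egl-6(lof), 188 ± 27 in flp-17oe and 232 ± 29.4 in flp-17oe egl-6(lof). The level in flp-17(lof) was 0.0671 times that of N2 and rested on 7 to 33 counts per library, and the array strains stood at 40.7 and 50.2 times N2. The egl-6 gene (WBGene00001175, chromosome X, 5931122 to 5934532, plus strand) had 6.03 ± 0.629 CPM in N2, 6.07 ± 0.284 in flp-17(lof), 2.81 ± 0.496 in egl-6(lof), 6.33 ± 0.838 in flp-17oe and 2.89 ± 0.380 in flp-17oe egl-6(lof). Part of the egl-6 transcript therefore stayed measurable in the receptor mutants, at 0.466 and 0.480 times N2. The gene myo-3, of a body wall muscle myosin heavy chain (WBGene00003515, chromosome V, 12226817 to 12234343, minus strand), was fixed beforehand because its promoter is on the array. It is therefore no neutral reference. Its level was 47.7 ± 4.75 CPM in N2, 52.3 ± 6.24 in flp-17(lof), 54.4 ± 7.63 in egl-6(lof), 44.7 ± 6.21 in flp-17oe and 47.2 ± 14.3 in flp-17oe egl-6(lof), and it passed no test.

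**Figure D1:**
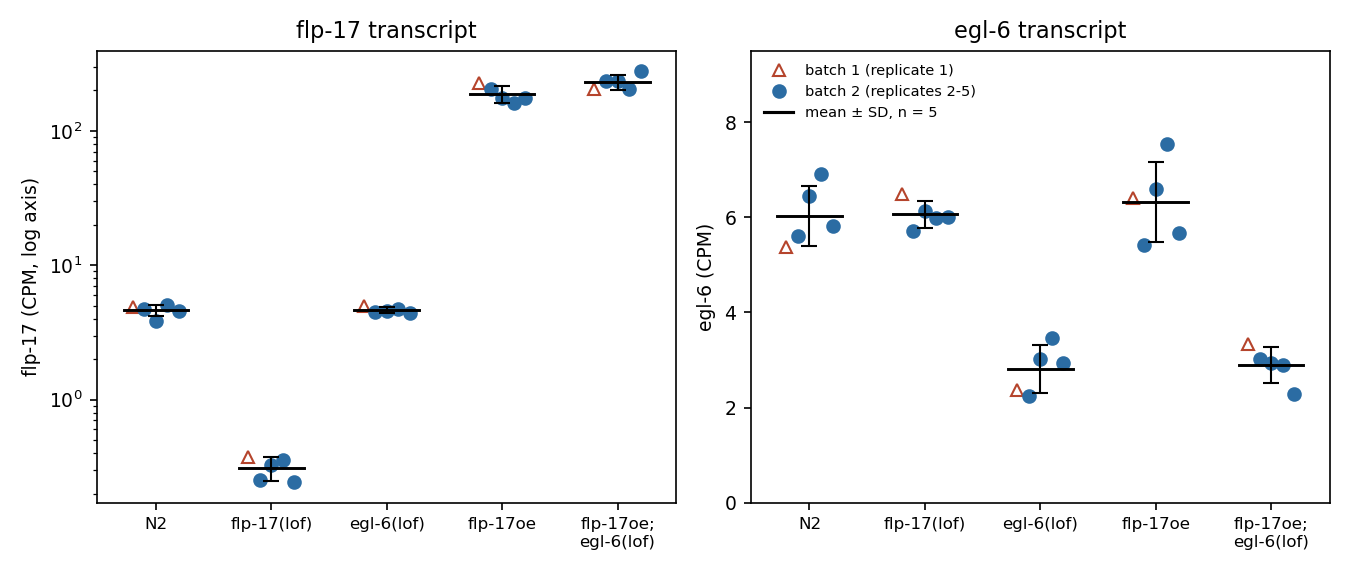
CPM of flp-17 (log axis) and egl-6 (linear axis) in each of the 25 libraries by genotype, triangles for batch 1 and circles for batch 2, with the mean and SD of 5 libraries. The flp-17 gene averaged 0.310 in flp-17(lof) and 188 and 232 in the array strains against 4.62 in N2, and egl-6 averaged 2.81 and 2.89 in the egl-6(lof) strains against 6.03.

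Loss of flp-17 was compared with N2 to find what depends on the peptide gene. Few genes differed. The UDP-glucuronosyltransferase gene ugt-64 on chromosome V rose to 79.2 ± 3.69 CPM from 24.1 ± 4.32 (log2 1.71, SE 0.11, adjusted p = 5.62e-10). The F-box gene fbxa-192 rose from 11.3 ± 1.14 to 28.1 ± 5.41 CPM (log2 1.3, SE 0.10) and sdc-3, a zinc finger gene of sex determination and dosage compensation, rose from 30.6 to 80.5 CPM (log2 1.39, SE 0.12, adjusted p = 5.3e-08). T05A12.4 rose by log2 1.13 (SE 0.14) and F36D3.1 by 0.55 (SE 0.07). The falls were flp-17 itself (log2 -3.92, SE 0.15, adjusted p = 9.98e-15), Y37E11B.5 (log2 -1.44, SE 0.06, from 33.2 CPM in N2), tcl-2, a gene of asymmetric T cell division (log2 -1.02, SE 0.08, from 13.4 to 6.60 CPM), and T16H12.2 (log2 -0.81, SE 0.11). C07G3.8 and C10C6.7 completed the 11 genes and were chosen for naming after their values were seen. C07G3.8 rose by log2 2.42 from 0.0617 CPM, and C10C6.7 fell by log2 1.11.

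In total 6 genes rose and 5 fell in flp-17(lof) at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg over 14634 genes), 9 of them by over 2-fold, against 390 genes with an unadjusted p under 0.05. Within batch 2 alone 14 genes passed. Among the 38 tested lists of genes, the 79 ribosomal protein genes were all higher, with a median log2 of 0.20 (camera adjusted p = 7.08e-14), but edgeR called 0 of them, 0 had an unadjusted p under 0.05, and DESeq2 called 0. Their adjusted p was 0.888 with an estimated correlation. Their median was -0.04 in batch 2 and -0.01 when flp-17(lof) replicate 1 alone was left out (adjusted p = 0.573). In that library the ribosomal protein score was 1.05, against -0.11 to 0.21 in the other libraries. The 29 FLP neuropeptide genes apart from flp-17 had a median log2 of 0.11 (camera adjusted p = 0.00637, 0.888 with an estimated correlation), which was 0.00 without flp-17(lof) replicate 1 (adjusted p = 0.696). The 27 early embryonic zygotic genes had a median of -0.13 (camera adjusted p = 1.54e-06, 0.128 with an estimated correlation), with 0 called by edgeR and by DESeq2 and 3 lower at an unadjusted p under 0.05. Of 288 F-box and MATH-BTB genes 31 were lower and 4 higher at an unadjusted p under 0.05, and DESeq2 called 1 higher and 0 lower. Their score difference was -0.15 (SE 0.06), and within batch 2 the camera adjusted p was 0.00160, or 0.268 with an estimated correlation.

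The receptor mutant egl-6(lof) was compared with N2 to find what depends on EGL-6. Sperm transcripts were higher: msp-33, msp-36 and msp-31, which encode major sperm proteins, rose by log2 2.48 (SE 0.51), 2.45 (SE 0.52) and 2.19 (SE 0.43), and msp-33 went from 1.81 to 5.46 CPM. The sperm TRP channel gene spe-41 rose from 3.18 to 5.16 CPM (log2 0.70, SE 0.11, adjusted p = 0.00136), with msp-76 at log2 2.25 (SE 0.51), gipc-1 at 2.19 (SE 0.50) and ssq-1, of a sperm-specific family, at 1.57 (SE 0.34). In flp-17oe egl-6(lof), where msp genes were lower than in egl-6(lof), spe-41 had 5.87 CPM. It thus did not move with the msp genes across genotypes. As in flp-17(lof), ugt-64 was raised, at 60.3 ± 4.91 CPM against 24.1 ± 4.32 (log2 1.32, SE 0.11, adjusted p = 2.64e-07), and so was fbxa-192, at 24.8 ± 0.848 CPM against 11.3 ± 1.14 (log2 1.13, SE 0.10). B0511.11 rose by log2 1.29 (SE 0.15). Falls were C10C6.7 (log2 -0.89, chosen for naming after its values were seen), sax-2, a Furry-like regulator of neurite growth, from 166 to 75.4 CPM (log2 -1.14, SE 0.13, adjusted p = 1.15e-05), egl-6 (log2 -1.10, SE 0.12), F56B3.2 (log2 -0.67, SE 0.08), the Nudix hydrolase gene ndx-2 (log2 -0.60, SE 0.13) and the CLASP gene cls-3 (log2 -0.56, SE 0.10). B0261.8, F28F8.7 and T10D4.6 stood at log2 -0.52, -0.44 and -0.38.

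The sperm list had 7 of 60 members rise over all genes, or 49 adjusted over the list alone, with 56 higher and a median log2 of 2.18 (camera adjusted p = 6.9e-38, 0.401 with an estimated correlation). DESeq2 called 44 of them, and edgeR 38 when flp-17(lof) replicate 1, a library of neither genotype, was left out. The single batch 1 libraries went the other way, with a sperm score of 2.06 in N2 and 0.98 in egl-6(lof), whereas batch 2 gave a difference of 2.25 (SE 0.32). Within batch 2, 49 of 58 members rose, the median was 2.85 and the adjusted p was 0.0333 with an estimated correlation. By part, the median log2 was 2.27 over 28 msp genes, 2.16 over 9 nspd genes, 1.98 over 7 ssp genes and 0.22 over 14 spe genes, and near-identical copies within the msp family leave the value of any single copy uncertain. Collagen genes had a median of 0.51 with 99 of 113 higher (camera adjusted p = 2.95e-18, 0.401 with an estimated correlation), and 24 rose adjusted over the list alone, while edgeR over all genes called 0 (5 without flp-17(lof) replicate 1), DESeq2 14, and 41 were higher at an unadjusted p under 0.05. Of 288 F-box and MATH-BTB genes 6 rose, or 10 adjusted over the list alone, among them fbxa-107 (log2 0.70, SE 0.07), fbxc-43 (log2 0.78, SE 0.13) and bath-13 (log2 1.52, SE 0.27), with an adjusted p of 0.625 with an estimated correlation. The 27 oocyte and eggshell genes had a median of -0.08 with 1 higher (camera adjusted p = 1.98e-05, 0.625 with an estimated correlation). The late embryonic cuticle genes had a median of 0.58 with 19 of 20 higher (camera adjusted p = 0.000138, 0.641 with an estimated correlation), but edgeR and DESeq2 called 0, with 4 higher at an unadjusted p under 0.05. Their score difference was 0.56 (SE 0.29), -0.06 between the batch 1 libraries and 0.72 (SE 0.28) in batch 2.

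Across all genes 71 changed in egl-6(lof), 62 higher and 9 lower (edgeR, adjusted p under 0.05), 44 of them by over 2-fold, and 693 changed within batch 2, 669 higher and 24 lower. The count rested on single libraries: it was 457 without N2 replicate 1, 251 without flp-17(lof) replicate 1 and 646 without egl-6(lof) replicate 1, and it was 35, 29, 29 and 41 without egl-6(lof) replicates 2, 3, 4 and 5, and 33, 30 and 32 without N2 replicates 3, 4 and 5. DESeq2 called 362 genes, a fit without the batch term 35 and a fit to the compared genotypes alone 39.

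**Figure D2:**
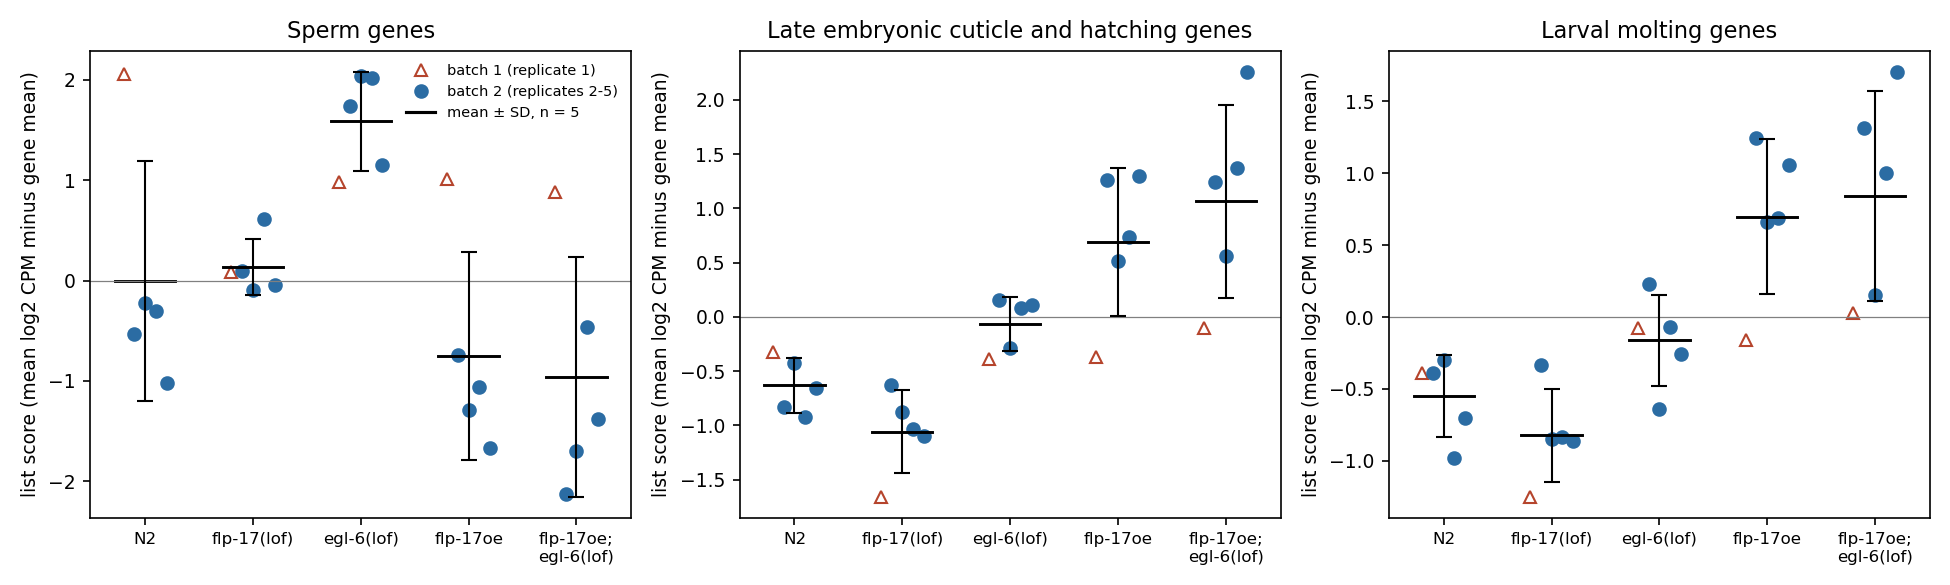
Score of the sperm, late embryonic cuticle and larval molting lists (mean log2 CPM of the members minus each gene's mean over all libraries) in each library by genotype, triangles for batch 1 and circles for batch 2, with the mean and SD of 5 libraries. The sperm score was 2.06 in the batch 1 library of N2 against -1.02 to -0.22 in its batch 2 libraries.

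Array animals were compared with N2 to find what flp-17 overexpression changes, with sorting and the other contents of the array as further differences. The array also holds the promoter of the body wall muscle gene myo-3, and no strain carried an array without flp-17. Effects of flp-17 therefore cannot be told apart from those of the other contents, for muscle genes as for others. Besides flp-17 (log2 5.34, SE 0.11, adjusted p = 1.05e-20), the largest rises by the naming rule were in cuticle collagens: sqt-1 by log2 4.01 (SE 1.01), rol-6 by 3.87 (SE 0.89), dpy-8 by 3.64 (SE 0.58), rol-8 by 3.41 (SE 0.74), col-168 by 3.20 (SE 0.46) and dpy-3 by 3.17 (SE 0.56). These started from low levels, dpy-8 going from 0.326 to 4.28 CPM. The aspartyl protease gene asp-12 rose from 34.7 to 242 CPM (log2 3.18, SE 0.23, adjusted p = 7.04e-09). The largest falls were K10C2.8 (log2 -1.47, SE 0.15), T16G1.7 (log2 -1.37, SE 0.37), the hedgehog-related grd-3 (log2 -1.25, SE 0.16, from 89.8 to 38.3 CPM), the collagens col-142 (log2 -1.25, SE 0.22) and col-124 (log2 -1.22, SE 0.23), ZK673.1 (log2 -1.12, SE 0.15), the acyl-CoA dehydrogenase gene acdh-2 (log2 -1.04, SE 0.13) and the arginine kinase gene argk-1 (log2 -1.04, SE 0.24).

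Genes of the late embryonic cuticle rose together in flp-17oe, 12 of 20 over all genes and 12 adjusted over the list alone, with a median log2 of 1.33 (camera adjusted p = 9.47e-09, 0.272 with an estimated correlation). Among them were lpr-3, a lipocalin of the apical matrix (log2 2.74, SE 0.44), and the collagen gene dpy-7 (log2 2.79, SE 0.48). Larval molting genes rose in 14 of 25 cases, or 15 with 1 fall adjusted over the list alone, with a median of 1.14 (camera adjusted p = 1.44e-07, 0.272 with an estimated correlation). Examples were mlt-11, which encodes a protein with protease inhibitor domains needed for molting (log2 2.79, SE 0.51, from 1.51 to 11.7 CPM), the patched-related ptr-4 (log2 2.31, SE 0.43) and the hedgehog-related wrt-10 and wrt-2 (log2 2.45, SE 0.46, and 2.46, SE 0.47). Both lists depended on batch 2: the molting score of flp-17oe minus N2 was 0.23 between the single batch 1 libraries and 1.5 (SE 0.28) in batch 2, and the late embryonic score -0.05 and 1.66 (SE 0.28). Collagen genes as a whole went both ways, 14 rising and 13 falling of 113 (18 and 21 adjusted over the list alone), with a median of 0.08 and a mean of 0.29 while camera leaned down (adjusted p = 0.950). Without flp-17(lof) replicate 1 there were 17 rises and 24 falls. The 60 sperm genes had a median of -0.95 (camera adjusted p = 3.15e-06, 0.564 with an estimated correlation), with 0 called by edgeR and by DESeq2 and 7 lower at an unadjusted p under 0.05.

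Body wall muscle genes fell in 8 of 20 cases, or 13 adjusted over the list alone, with a median log2 of -0.29 (camera adjusted p = 7.18e-08, 0.186 with an estimated correlation) and score differences of -0.31 in batch 1 and -0.26 (SE 0.08) in batch 2. Troponin T gene tnt-2 went from 457 to 261 CPM (log2 -0.80, SE 0.09, adjusted p = 5.74e-06), and the troponin I gene unc-27, the tropomyosin gene lev-11 and the actin gene act-4 fell by log2 0.60 (SE 0.12), 0.45 (SE 0.08) and 0.40 (SE 0.09). Immune effector genes rose in 20 of 81 cases and fell in 2, or 22 and 3 adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.00125, 0.564 with an estimated correlation). The effectors of the PMK-1 p38 pathway T24B8.5, C17H12.8 and irg-4 rose by log2 2.17 (SE 0.23), 1.45 (SE 0.15) and 1.35 (SE 0.14), and the C-type lectin gene clec-67 rose by 1.83 (SE 0.12, adjusted p = 1.44e-09). Of 131 C-type lectin genes 24 rose and 3 fell, or 31 and 8 adjusted over the list alone, with a median of 0.00, a mean of -0.01 and a camera test leaning up (adjusted p = 0.060). Without flp-17(lof) replicate 1 there were 25 rises and 6 falls, and the adjusted p was 0.0345. The most abundant riser among those named was clec-63, from 380 to 704 CPM (log2 0.90, SE 0.10).

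The intracellular pathogen response list rose in 7 of 27 members, or 9 adjusted over the list alone, with a median log2 of 0.29 (camera adjusted p = 3.58e-06, 0.186 with an estimated correlation, 0.0219 within batch 2). Its named members were skr-5 (log2 1.53, SE 0.31), eol-1 (log2 1.73, SE 0.38), pals-33 and pals-39 (log2 1.52 and 1.65), all at low levels, with skr-5 at 0.469 CPM in flp-17oe. UDP-glucuronosyltransferase genes rose in 11 of 61 cases, or 15 with 1 fall adjusted over the list alone, led by ugt-18 (log2 3.77, SE 0.45), with an adjusted p of 0.531 with an estimated correlation. The glutathione S-transferase gene gst-24 rose from 1.18 to 7.55 CPM (log2 2.66, SE 0.24, adjusted p = 1.82e-07), and the superoxide dismutase gene sod-3 fell (log2 -1.04, SE 0.20). In the intestine list 5 of 19 rose, or 5 with 2 falls adjusted over the list alone, and 5 with 2 falls without flp-17(lof) replicate 1, among them the protease genes asp-5 (log2 0.53, SE 0.09), asp-3 (log2 0.44, SE 0.08) and cpr-4 (log2 0.64, SE 0.12). The 79 ribosomal protein genes had a median of -0.26 (camera adjusted p = 1.34e-11, 0.531 with an estimated correlation). Of these edgeR called rps-22 lower over all genes and 0 adjusted over the list alone, DESeq2 called 4 lower, and 22 were lower at an unadjusted p under 0.05. Without flp-17(lof) replicate 1 edgeR called 16 lower.

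Array animals, which were also sorted, differed from N2 in 1018 genes, 699 higher and 319 lower (edgeR, adjusted p under 0.05), with 305 over 2-fold and 1116 within batch 2. Leaving out flp-17oe replicate 5 reduced the count to 673, the lowest for any single library.

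Removing the receptor from array animals, flp-17oe egl-6(lof) against flp-17oe, asks which transcripts of array animals depend on EGL-6. Here fbxa-192 went from 9.38 ± 0.945 to 26.7 ± 2.3 CPM (log2 1.51, SE 0.10, adjusted p = 1.01e-09) and ugt-64 from 24.0 ± 3.93 to 60.3 ± 6.38 CPM (log2 1.33, SE 0.11, adjusted p = 6.38e-08), so both genes were higher with egl-6(lof) in either background. Other large rises were the bZIP gene zip-8 (log2 1.37, SE 0.31), F46E10.2 (log2 1.29, SE 0.23), pitr-3 (log2 1.22, SE 0.19), Y82E9BR.17 (log2 1.19, SE 0.25), clec-266 (log2 1.17, SE 0.22) and the arrestin-domain gene arrd-1 (log2 1.11, SE 0.26). F25E5.1 fell from 132 to 50 CPM (log2 -1.40, SE 0.08, adjusted p = 6.15e-11), followed by B0511.11 (log2 -1.21, SE 0.15), egl-6 (log2 -1.13, SE 0.12) and sax-2, from 156 to 81.7 CPM (log2 -0.94, SE 0.13). Further falls were F36D3.1 (log2 -0.91, SE 0.07), the stearoyl-CoA desaturase gene fat-7, from 133 to 79.8 CPM (log2 -0.74, SE 0.18), the aspartic protease gene hrg-7 of heme signalling (log2 -0.68, SE 0.17, adjusted p = 0.0700 with replicate numbers as a block) and R08E5.3 (log2 -0.63, SE 0.10). The array's flp-17 level did not pass the test (log2 0.31, adjusted p = 0.0914).

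F-box and MATH-BTB genes rose as a group, 26 of 288 rising and fbxa-125 falling over all genes, or 67 rising and 1 falling adjusted over the list alone. Their median log2 was 0.20, and the call held with an estimated correlation (camera adjusted p = 6.8e-15, 0.0148 with an estimated correlation), the single one of the 75 camera calls over all comparisons that did. The score difference was 0.42 between the batch 1 libraries and 0.28 (SE 0.04) within batch 2, where the adjusted p was 0.00773 with an estimated correlation. Named members were fbxb-19 (log2 1.84, SE 0.31), fbxa-107 (log2 0.82, SE 0.07, adjusted p = 1.72e-07) and bath-1 (log2 0.52, SE 0.08), and near-identical copies in these families leave single values uncertain. Early embryonic zygotic genes rose in 4 of 27 cases, or 9 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 3.55e-06, 0.0796 with an estimated correlation). They were vet-6 (log2 0.75, SE 0.13), sdz-28 (log2 1.03, SE 0.20), the T-box gene tbx-11 (log2 0.84, SE 0.18) and pes-10 (log2 0.60, SE 0.15). The lipase list rose in 2 of 21 members, or 6 adjusted over the list alone (0.175 with an estimated correlation as adjusted p), the lysosomal lipase gene lipl-1 by log2 1.92 (SE 0.40) and lipl-5 by 0.45 (SE 0.10). Immune effectors rose in 3 of 81 cases (10 without flp-17(lof) replicate 1), or 10 adjusted over the list alone (adjusted p = 0.669 with an estimated correlation), namely irg-5 (log2 0.73, SE 0.10), the lysozyme gene lys-7 (log2 0.53, SE 0.13) and clec-67 (log2 0.46, SE 0.11). The metallothionein gene mtl-1 rose by log2 1.69 (SE 0.27), the linker histone gene his-24 by 0.98 (SE 0.20) and the hatching protease gene hch-1 by 1.67 (SE 0.40).

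**Figure D3:**
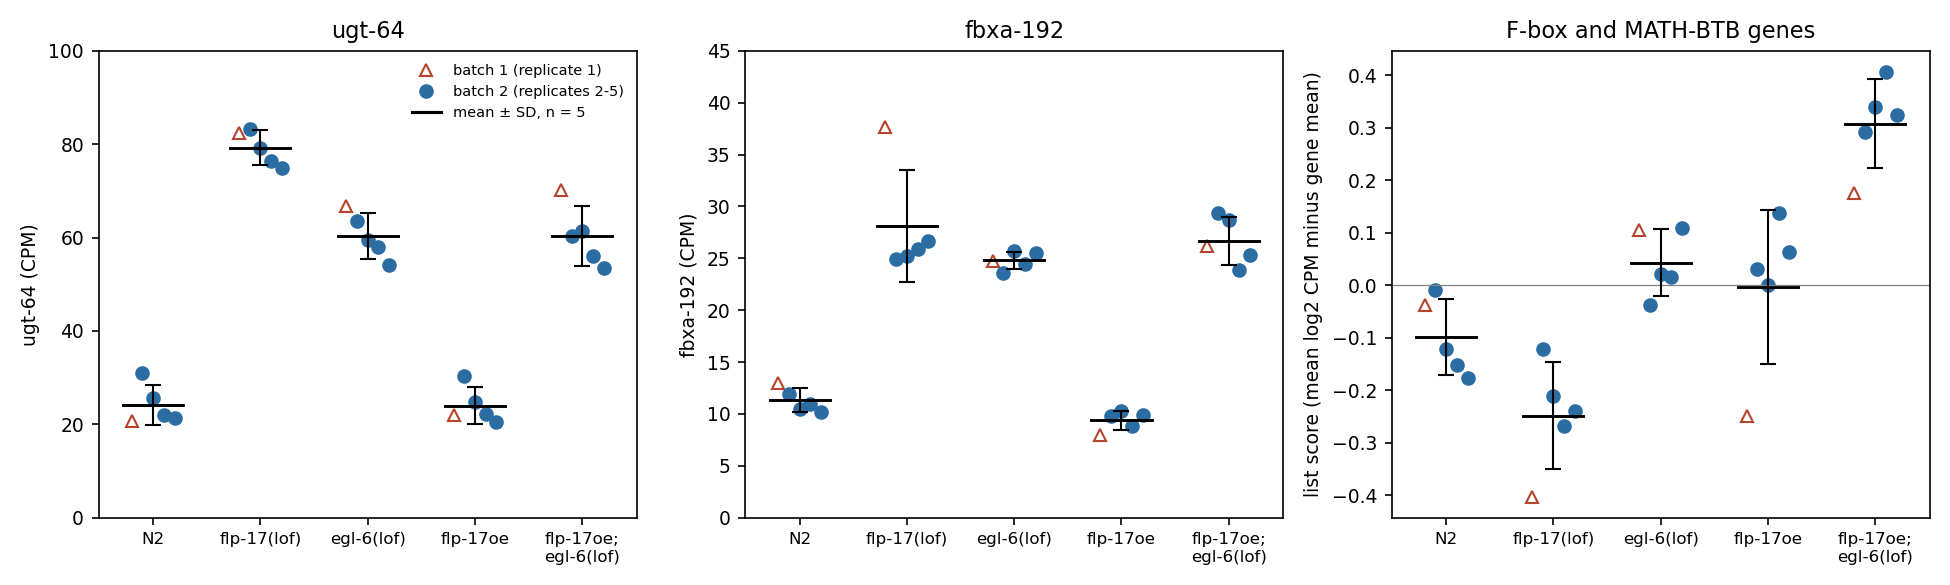
CPM of ugt-64 and fbxa-192 and the score of the F-box and MATH-BTB list (mean log2 CPM minus each gene's mean over all libraries) in each library by genotype, triangles for batch 1 and circles for batch 2, with the mean and SD of 5 libraries. The ugt-64 gene averaged 24.1 in N2 and 24.0 in flp-17oe and 60.3 to 79.2 in the other 3 genotypes.

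Over all genes this comparison called 204, 172 higher and 32 lower (edgeR, adjusted p under 0.05), 65 of them over 2-fold, and 301 within batch 2. The count was 322 without flp-17(lof) replicate 1, a library of neither genotype, 117, 73 and 130 without flp-17oe replicates 1, 3 and 5, and 115, 87 and 128 without flp-17oe egl-6(lof) replicates 2, 3 and 5. DESeq2 called 350 and a fit to the compared genotypes alone 125.

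With the receptor absent in both arms, flp-17oe egl-6(lof) against egl-6(lof) asks what the array, again with sorting, changes without EGL-6. The gene flp-17 rose by log2 5.65 (SE 0.11, adjusted p = 3.66e-21), and collagens were again the largest rises, with rol-6 at log2 4.13 (SE 0.83), col-17 at 3.59 (SE 0.77), sqt-1 at 3.59 (SE 0.91), dpy-8 at 3.25 (SE 0.55) and rol-8 at 3.08 (SE 0.67). They were followed by gst-24 (log2 2.93, SE 0.23, adjusted p = 3.76e-08) and the immune effector T24B8.5 (log2 2.59, SE 0.23, from 5.13 to 30.8 CPM). Sperm transcripts made up most of the largest falls: msp-36 went from 8.42 to 1.12 CPM (log2 -3.65, SE 0.56), msp-81, msp-57, msp-19 and msp-152 to log2 -3.62, -3.53, -3.49 and -3.47, and ssq-2 from 13.8 to 2.08 CPM (log2 -3.54, SE 0.60). C04G2.9 fell by log2 3.56 (SE 0.63) and the collagen gene col-133 by 3.87 (SE 0.78).

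The sperm list fell in 50 of 60 members, or 53 adjusted over the list alone, with a median log2 of -3.32 (camera adjusted p = 1.52e-33, 0.207 with an estimated correlation). Its score difference was -0.10 between the batch 1 libraries and -3.15 (SE 0.32) within batch 2. Body wall muscle genes fell in 13 of 20 cases, or 14 adjusted over the list alone, with a median of -0.48 (camera adjusted p = 7.47e-13, 0.140 with an estimated correlation), and tnt-2 went from 462 to 233 CPM (log2 -1.0, SE 0.09, adjusted p = 2.77e-07), with dim-1, act-4 and lev-11 at -0.55, -0.60 and -0.55. Score differences for muscle were -0.58 in batch 1 and -0.38 (SE 0.08) in batch 2. Late embryonic cuticle genes rose in 13 of 20 cases, or 14 adjusted over the list alone, with a median of 1.21 (camera adjusted p = 2.44e-07, 0.332 with an estimated correlation), among them dpy-7 (log2 2.37, SE 0.44) and lpr-3 (log2 2.3, SE 0.41). Larval molting genes rose in 15 of 25 cases with 1 fall, or 16 and 3 adjusted over the list alone, with a median of 1.02 (camera adjusted p = 5.26e-05, 0.400 with an estimated correlation). Named members were wrt-2 (log2 3.10, SE 0.46), the Period homologue lin-42 (log2 1.07, SE 0.20) and ptr-4 (log2 2.1, SE 0.40), while the adult cuticle collagen gene bli-6 fell (log2 -2.70, SE 0.37). The score differences of late embryonic and molting genes were 0.28 and 0.11 in batch 1 and 1.34 (SE 0.28) and 1.23 (SE 0.28) in batch 2.

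Immune effectors rose in 26 of 81 cases and fell in 4, or 29 and 4 adjusted over the list alone, with a median log2 of 0.34 (camera adjusted p = 2.44e-07, 0.408 with an estimated correlation). The genes clec-67, irg-4 and irg-5 rose by log2 1.96 (SE 0.12), 1.47 (SE 0.14) and 1.07 (SE 0.10). Of 113 collagen genes 17 rose and 40 fell, or 19 and 44 adjusted over the list alone, with a median of -0.30 (camera adjusted p = 5.26e-05, 0.597 with an estimated correlation) and falls in col-129 (log2 -2.81, SE 0.34), col-141 (log2 -2.07, SE 0.21), col-124 (log2 -2.04, SE 0.24) and col-142 (log2 -2.03, SE 0.22). Of 288 F-box and MATH-BTB genes 33 rose and 3 fell, or 31 and 3 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 2.44e-07, 0.187 with an estimated correlation), including fbxa-182 (log2 0.94, SE 0.11), math-45 (log2 1.21, SE 0.17) and bath-47 (log2 1.58, SE 0.25). Nuclear oxidative phosphorylation genes fell in 7 of 33 cases over all genes and over the list alone, by small amounts such as log2 -0.19 (SE 0.04) for nuo-4 and -0.18 (SE 0.04) for cyc-1 (camera adjusted p = 1.53e-08, 0.313 with an estimated correlation). C-type lectin genes split into 30 rises and 32 falls of 131, or 35 and 38 adjusted over the list alone, with a median of 0.05, a mean of -0.67 and a camera test leaning up (adjusted p = 0.644).

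This comparison called 2108 genes, 881 higher and 1227 lower (edgeR, adjusted p under 0.05), with 1044 over 2-fold and 2351 within batch 2.

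The interaction asks whether the array's effect differed with and without the receptor. It passed for 13 genes, 12 of them with a lower array effect in egl-6(lof) (edgeR, adjusted p under 0.05), 6 over 2-fold. F25E5.1 rose by log2 1.44 with the array in wild-type egl-6 and stood at 0.13 in egl-6(lof), a difference of -1.31 (SE 0.11, adjusted p = 2.94e-07). B0511.11 differed by -2.51 (SE 0.22, adjusted p = 3.09e-07), from 1.84 to -0.67. Other differences were F36D3.1 at -0.71 (SE 0.10), R08E5.3 at -0.96 (SE 0.14), C17B7.5 at -1.0 (SE 0.19), the aspartyl protease gene asp-8 at -0.88 (SE 0.17), M04F3.3 at -0.69 (SE 0.13) and tub-2 at -0.61 (SE 0.11). The F-box gene fbxa-125 had 13 to 25 counts per flp-17oe library and 0 to 2 per N2 library, so its fitted difference of -6.0 depends on the prior. Y34F4.3 at 2.08, F38B6.4 at -0.48, Y51H7C.13 at -1.47 and tag-344 at -3.49 were chosen for naming after their values were seen. The sperm list had a median of -2.23 (camera adjusted p = 8.75e-26, 0.338 with an estimated correlation, 0.0460 within batch 2), and 36 of its 60 genes fell adjusted over the list alone, while edgeR over all genes called 0, DESeq2 1, and 42 were lower at an unadjusted p under 0.05. Between the single batch 1 libraries the array's sperm score difference was -1.05 with wild-type egl-6 and -0.10 in egl-6(lof). In batch 2 the order was the opposite, at -0.67 and -3.15 (SE 0.32 each).

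Within batch 2 the interaction called 168 genes, and the count was 154 without egl-6(lof) replicate 1, 25 without flp-17oe egl-6(lof) replicate 1 and 27 without N2 replicate 2. It was 7, 8 and 8 without egl-6(lof) replicates 2, 4 and 5, 8 without flp-17oe egl-6(lof) replicate 2 or 4, 8, 7 and 6 without N2 replicates 3, 4 and 5, 8 without flp-17(lof) replicate 4 and 7 without flp-17oe replicate 4. DESeq2 called 36 genes, a fit without the batch term 6 and a fit with a replicate block 7. With the block tub-2, asp-8, C17B7.5, F38B6.4, Y51H7C.13 and tag-344 were no longer called, at adjusted p of 0.0603 to 0.0620.

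The changes with the array were alike with and without the receptor across genes, which are not independent replicates. Pearson's r between the log2 changes was 0.699 and Spearman's rho 0.608. Sorting and the whole array were part of both comparisons, so this likeness cannot be credited to flp-17 apart from sorting or the other array contents. Both comparisons called 418 genes higher, where 42.0 would fall together by chance, and 202 lower, where 26.8 would, and 1 gene was called in opposite directions. Of 1017 genes called in wild-type egl-6, with flp-17 and egl-6 left out, 983 (96.7%) had the same sign in egl-6(lof). The effect of egl-6(lof) was less alike between backgrounds, with r -0.141 and rho 0.115, -0.204 to 0.110 leaving out one replicate at a time and 0.0202 under a stricter count filter. It shared 16 higher genes, with 0.729 by chance, and 3 lower genes, with 0.0169 by chance.

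**Figure D4:**
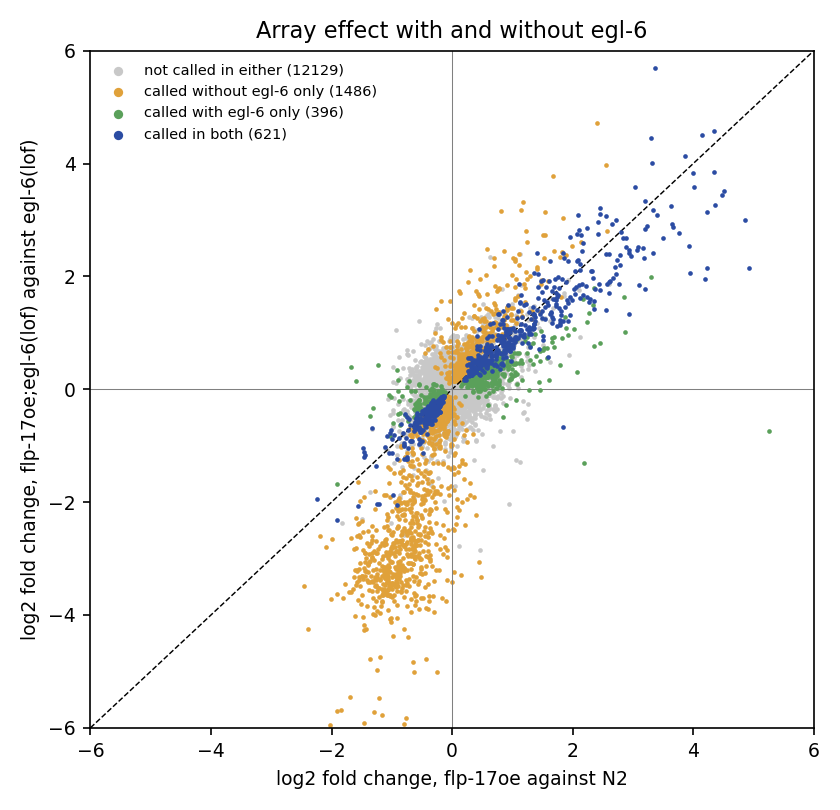
Log2 change with the array and sorting in wild-type egl-6 (horizontal) against that in egl-6(lof) (vertical), each point a gene, coloured by whether edgeR called it in both (621), in egl-6(lof) alone (1486), in wild-type egl-6 alone (396) or in neither comparison (12129). The dashed line marks equal change, flp-17 and egl-6 are left out, and 42 points beyond the axis limits of 6 are not drawn.

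Loss of the peptide gene and loss of its receptor were compared with each other through N2. Both raised ugt-64 and fbxa-192 and lowered C10C6.7, a gene chosen for naming after its values were seen, at -1.11 in flp-17(lof) and -0.89 in egl-6(lof). Within batch 2 the sperm list of flp-17(lof) also leaned up, with a median log2 of 0.77. Its camera adjusted p was 3.74e-18, but 0.380 with an estimated correlation, and edgeR called 0 of 58 members. Over both batches its score difference was 0.14 (SE 0.48). Across genes r was 0.0399 and rho 0.222. The shared N2 libraries alone gave r of 0.180 to 0.233 in 20 simulations without any effect. Their mean rho was 0.0437, under the observed rho, with a mean of 0 genes called higher and 0 lower in both. The simulated genes varied independently and without a batch difference, unlike the data. Splitting the N2 libraries between the comparisons gave a mean r of -0.146 over 20 splits, from -0.511 to 0.352. Leaving out replicate 1 raised r to 0.502. The array's effect against that of flp-17(lof) had r -0.0481, with 1 gene called higher and 2 lower in both. Splitting the N2 libraries gave a mean r of -0.295 over 20 splits, from -0.428 to -0.129.

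Genes around the mutated loci were compared with genes elsewhere. Within 2 Mb of flp-17, with the gene itself left out, edgeR called 0 of 162 genes in flp-17(lof), against 10 of 14469 elsewhere (2-sided Fisher's exact p = 1). There 6 had an unadjusted p under 0.05, against 383 elsewhere, and DESeq2 called 0. Within 2 Mb of egl-6, 1 of 528 genes was called in egl-6(lof) against N2, T22B7.7, chosen for naming after its values were seen, against 69 of 14103 elsewhere (exact p = 0.521). There 38 against 1082 had an unadjusted p under 0.05, and DESeq2 called 7 of its 362 genes there. In flp-17oe egl-6(lof) against flp-17oe, 8 of 528 were called there against 195 of 14103 elsewhere (exact p = 0.705). At an unadjusted p under 0.05 there were 78 against 1431, a larger share than elsewhere (exact p = 0.00101, a test chosen after the counts were seen), and DESeq2 called 15 of its 350 genes there. A window of 5 Mb around egl-6 held 1 called gene of 1242 in egl-6(lof) against N2, a smaller share than elsewhere (exact p = 0.0290). At an unadjusted p under 0.05 it held 64 against 1056 elsewhere, again a smaller share (exact p = 0.000345). In flp-17oe egl-6(lof) against flp-17oe it held 166 against 1343, a larger share (exact p = 0.000361).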

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

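The tests in this part, the splits of the libraries among them, were chosen only after the results were seen, except the test on the spe genes, which was set before its result was seen. Among 70 groups of 5 libraries checked for a library far from the others, 7 had one, where chance flags about 1 in 20 groups, or 3.5.

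Of the 7, 4 were in flp-17(lof) replicate 1. Its ribosomal RNA share was 9.5%, its scaling factor 0.740, its ribosomal protein score 1.05 and its immune effector score 0.28 against -0.34 to -0.26 in the other libraries of the genotype. In egl-6(lof) replicate 1 the body wall muscle score was 0.43 against 0.04 to 0.11 in the others. The sperm score was 2.06 in N2 replicate 1 against -1.02 to -0.22, and 0.61 in flp-17(lof) replicate 4 against -0.09 to 0.09.

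For 13 genes the array's effect in egl-6(lof) minus that with wild-type egl-6 passed the interaction test (edgeR). On the log2 scale it was -1.31 for F25E5.1, -2.51 for B0511.11, -0.71 for F36D3.1, -0.96 for R08E5.3, 2.08 for Y34F4.3, -6.0 for fbxa-125, -0.69 for M04F3.3, -0.61 for tub-2, -0.48 for F38B6.4, -1.0 for C17B7.5, -0.88 for asp-8, -1.47 for Y51H7C.13 and -3.49 for tag-344.

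Molting and late embryonic cuticle genes were higher in both array genotypes. An action of the array through EGL-6, for example by retained embryos, would need the receptor. The late embryonic score was still 1.13 (SE 0.29) higher in flp-17oe egl-6(lof) than in egl-6(lof), so the pattern arose there without EGL-6. Sorting was part of that comparison, and the interaction of the score was -0.19 (SE 0.42). A part through EGL-6 in flp-17oe is therefore not excluded. Fourth-stage larvae among the array animals would carry sperm transcripts. The sperm score of flp-17oe egl-6(lof) against egl-6(lof) was -2.54 (SE 0.48), but -0.10 between its batch 1 libraries. It was -0.75 (SE 0.48) for flp-17oe against N2, within 2 SE of 0. Within batch 2 the values were -3.15 (SE 0.32) and -0.67 (SE 0.32), both lower by over 2 SE, which goes against larvae there. Fewer sperm transcripts in the adults would still hide a small share of larvae, so these stay open. Sorting and replating, or late embryos and hatched larvae carried with the array animals, could still account for the pattern: only array animals were sorted, and the single batch 1 libraries, whose molting scores differed by 0.23, have no spread to judge it by. An effect of flp-17 apart from EGL-6 cannot be told apart from sorting or from the other contents of the array in this design and stays untested.

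Sperm genes were higher in egl-6(lof) than in N2. The difference between batches as the whole source is argued against by batch 2 alone, where the sperm score differed by 2.25 (SE 0.32). Reads shared among near-identical msp copies were judged in a pair of ways. The test set beforehand, the median of the 14 spe genes, gave 0.22 (SE 0.26), under the 0.5 that shared reads predicted and with 0.5 within 2 SE. It stays undecided (within batch 2 the median was 0.44, with 5 of 13 called). The msp genes summed over copies differed by log2 2.96 within batch 2, which argues against mere redistribution among copies there. Between the single batch 1 libraries the sum was higher in N2, at 173 CPM against 74.5 in egl-6(lof). Collection at a younger adult age stays open. The molting score was 0.39 (SE 0.27) higher, a difference within 2 SE of 0, which cannot decide it. The collagen score, not part of this test, was 0.79 (SE 0.23) higher, and 0.81 (SE 0.28) higher within batch 2. Whether age accounts for that was not tested. In array animals no such rise was seen: the sperm score of flp-17oe egl-6(lof) against flp-17oe differed by -0.21 (SE 0.48). Within batch 2 it differed by -0.23 (SE 0.32). A biological effect of the receptor on sperm number or retention in animals without the array is in the design and stays open, untested.

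The genes ugt-64 and fbxa-192 were higher in each strain with flp-17(lof) or egl-6(lof). Chance values of the shared N2 libraries are argued against by flp-17oe egl-6(lof) against flp-17oe, which uses no N2 library and gave log2 1.33 (SE 0.11) for ugt-64. A variant of the strain background near either gene could be involved. Of 16 other genes within 50 kb 1 was called in flp-17(lof), C07G3.8, which is more than elsewhere (Fisher's exact p = 0.00980). It is 1 of the 9 genes around ugt-64 and not of the 7 around fbxa-192. In flp-17oe egl-6(lof) against flp-17oe, C07G3.8 and lys-7 were called near ugt-64 (edgeR adjusted p = 0.0232 and 0.0444). Against N2, lys-7 stood at log2 0.08 in flp-17(lof) and -0.06 in egl-6(lof). Near fbxa-192, Y6G8.2 (named after its values were seen) stood uncalled at log2 0.39, 0.65 and 0.41 in flp-17(lof), egl-6(lof) and the array pair. In flp-17oe against N2 it was called, at log2 1.18. So few genes cannot separate a shared variant from shared regulation. Loss of the peptide or its receptor is the biological explanation in the design, and it stays open beside the variant.

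Other splits of the libraries were counted against the real one, 50 splits for each comparison. They did not keep batch balanced between groups. In a mixed split the real differences between genotypes also count as spread, which lowers its calls. For flp-17(lof) against N2 the real 11 genes, flp-17 among them, compare with at most 0 in another split. The call of flp-17 was given by the strain itself. Of 50 splits 1, the real one, gave as many, a share under 0.05. With 50 splits no smaller share could be seen. The interaction gave 13 genes against at most 0, with 1 split as large, but these splits do not keep the pairs of flp-17oe and flp-17oe egl-6(lof), and the replicate block called 7. In the real splits 390 and 1074 genes had an unadjusted p under 0.05 by edgeR. For flp-17oe against N2 the values were 1018 and at most 246, and for flp-17oe egl-6(lof) against egl-6(lof) 2108 and at most 1499, each with 1 of 50 splits as large, a share under 0.05. For flp-17oe egl-6(lof) against flp-17oe, where the replicate numbers pair the libraries, they were 204 and at most 17, with 1 split as large. The 17 came from the 44 splits that part fewer than 5 numbers, and the 5 other splits that part all 5 gave at most 0, too few for a share under 0.05. For flp-17oe against N2 only 2 other splits part all 5 numbers, with at most 0 genes. A pairing there would leave too few splits as well. For egl-6(lof) against N2 the real 71 was exceeded by another split with 302, 2 of 50 being as large, which is under 0.05. That split exchanged egl-6(lof) replicate 1 with N2 replicate 4 and called several times the real count, which points to a structure of the samples that follows batch 1, and within batch 2 the comparison called 693.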

How the results depend on the processing

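No other fit and no left-out replicate number reversed a named gene (single left-out libraries were judged on total counts of genes and, for flp-17(lof) replicate 1, on lists), but 3 lists of flp-17(lof) against N2 changed direction without replicate 1, none of them past the threshold there. Leaving out a replicate, the camera adjusted p ranged from 7.75e-22 to 0.141 for ribosomal protein genes, 0.000155 to 0.403 for nuclear oxidative phosphorylation genes and 1.58e-05 to 0.999 for oxidative stress genes, the highest being without replicate 1. Leaving out flp-17(lof) replicate 1 alone took their medians from 0.20, 0.06 and 0.12 to -0.009, -0.006 and -0.002 (camera adjusted p = 0.573, 0.899 and 0.781), so these calls depended on that library. All alternatives were planned. Of the 288 results for named genes, 286 kept direction and call under DESeq2, 284 under DESeq2-type size factors, 264 without a count filter, 282 under the stricter filter, 276 with a replicate block, 247 without the batch term and 244 in fits to the compared genotypes alone. Leaving out replicates 1 to 5 in turn kept 277, 238, 204, 200 and 202. Of 75 list calls, 73 to 75 were kept under the other fits and 59 to 67 without a replicate, but 1 with an estimated correlation, which ended 74.

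Counts of changed genes moved by over 1.5 times as follows. For egl-6(lof) against N2 (71) the fit without the batch term gave 35, the fit to the compared genotypes alone 39 and DESeq2 362. For flp-17oe egl-6(lof) against flp-17oe (204) the compared genotypes alone gave 125 and DESeq2 350. For the interaction (13) the fit without batch gave 6, the replicate block 7 and DESeq2 36. The correlation of the egl-6(lof) effect between backgrounds moved from -0.141 to 0.0202 under the stricter filter, which drops genes with few counts. The window of 5 Mb around egl-6 in egl-6(lof) against N2 gave an exact p of 0.0290, with 1 gene called. Except for the smaller fits, which have fewer libraries to estimate the spread, the cause was not tested.

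Leaving out a library or a replicate number, the counts ranged from 10 to 14 for flp-17(lof) against N2, 17 to 693 for egl-6(lof) against N2, 411 to 1416 for flp-17oe against N2, 18 to 322 for flp-17oe egl-6(lof) against flp-17oe, 1321 to 2453 for flp-17oe egl-6(lof) against egl-6(lof) and 2 to 168 for the interaction. Correlations ranged from 0.651 to 0.732 for the array with and without egl-6, -0.204 to 0.110 for egl-6(lof) with and without the array, -0.0866 to 0.502 for flp-17(lof) and egl-6(lof), and -0.0677 to 0.108 for the array and flp-17(lof).

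The replicate block presumes that equal replicate numbers belong together. Of 50 pairs of libraries with the same number in different genotypes 32 correlated above 0.1, from -0.41 to 0.66, and 14 of 25 libraries correlated best with their own number, against 5 expected for unrelated numbers. This hints at a partial pairing in the data, which the labels do not give, though batch was not removed from these correlations. Batch 2 was not uniform either. Ribosomal RNA made up 1.65% to 3.12% of counts in replicate 2 of the genotypes. In replicates 3 to 5 it was 0.276% to 0.619%, apart from 1.74% in N2 replicate 3. Values within batch 2 can therefore still mix sets of replicates. Only between flp-17oe and flp-17oe egl-6(lof) did all 5 pairs exceed 0.1, and there the block called 225 genes in place of 204 and, among named genes and lists, ended the calls of hrg-7 and of the vitellogenin list (adjusted p = 0.0637). At this depth and number of replicates changes of 2-fold and less were often missed, as 57.1% of simulated genes changed 1.5-fold and 64.6% of those changed 2-fold were recovered.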

Other observations

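The tests named in this part were planned, but the chromosome I genes and C07G3.8 were chosen after their values were seen.

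Some lists of neuronal genes had members called higher in flp-17oe than in N2, a comparison that includes sorting. Pan-neuronal genes rose in 3 of 17 cases (6 without flp-17(lof) replicate 1), or 10 adjusted over the list alone, with a median log2 of 0.32 (edgeR, camera adjusted p = 3.15e-06, 0.231 with an estimated correlation): the synaptic vesicle genes rab-3 (log2 0.72, SE 0.14) and snt-1 (log2 0.64, SE 0.16) and the neuropeptide convertase gene egl-3 (log2 0.38, SE 0.09). In the list of URX, AQR and PQR oxygen-sensing neurons 2 of 7 rose, or 4 adjusted over the list alone, with a median of 0.66 (camera adjusted p = 0.00193, 0.186 with an estimated correlation), the soluble guanylate cyclase gene gcy-32 by log2 0.97 (SE 0.24) and the aryl hydrocarbon receptor gene ahr-1 by 0.95 (SE 0.24). Egg-laying circuit genes rose in 3 of 22 cases, or 5 adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.0104, 0.448 with an estimated correlation): the ERG potassium channel gene unc-103 (log2 0.53, SE 0.14), the POU factor gene unc-86 (log2 1.00, SE 0.27) and the muscarinic receptor gene gar-2 (log2 0.60, SE 0.18). Without the receptor, in flp-17oe egl-6(lof) against egl-6(lof), the pan-neuronal score was 0.18 (SE 0.08) higher. The oxygen-sensing score was 0.46 (SE 0.13) and the egg-laying score 0.11 (SE 0.09) higher, and the interaction of each score was within 2 SE of 0. Other lists of neurons and their signals had few or no calls in flp-17oe against N2. Of 59 NLP neuropeptide genes edgeR called 2 higher, and DESeq2 5 higher and 1 lower (10 higher and 2 lower at an unadjusted p under 0.05), and of 24 insulin-like peptide genes each called 2 higher and 1 lower (4 and 1 unadjusted). Of 10 BAG neuron genes and 29 FLP genes both called 0 (3 and 7 higher at an unadjusted p under 0.05), of 63 neuropeptide receptor genes edgeR called 1 lower and DESeq2 0 (4 higher and 1 lower unadjusted), and of 23 biogenic amine genes both called 1 lower (7 higher and 2 lower unadjusted).

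In the fatty acid oxidation list of 32, flp-17oe against N2 had 1 rise and 3 falls (2 and 7 without flp-17(lof) replicate 1), or 2 and 7 adjusted over the list alone (camera adjusted p = 0.0215, 0.186 with an estimated correlation), and flp-17oe egl-6(lof) against egl-6(lof) 1 and 8, or 2 and 8 (camera adjusted p = 0.0493, 0.0561 without flp-17(lof) replicate 1, 0.207 with an estimated correlation). The thiolase gene kat-1 fell by log2 0.33 (SE 0.05) and 0.28 (SE 0.05), acdh-2 by 1.04 (SE 0.13) and 1.14 (SE 0.13), while ech-9 rose by 2.67 (SE 0.39) and 1.97 (SE 0.37). In flp-17oe against N2 the fatty acid synthesis list of 31 had 1 rise, the desaturase gene fat-2 (log2 0.37, SE 0.06), and 1 fall, fat-3 (log2 -0.38, SE 0.09), over all genes and over the list alone (camera adjusted p = 0.311). The vitellogenin list of 6 had 2 falls in each way, vit-1 and vit-3 by log2 0.40 (SE 0.10) and 0.34 (SE 0.10) (camera adjusted p = 0.620).

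Of the 13 interaction genes, 3 lie side by side on chromosome I: tag-344 (10644245 to 10645617), fbxa-125 (10646478 to 10647841) and B0511.11 (10648600 to 10654237). They stood at log2 2.18, 5.26 and 1.84 in flp-17oe against N2 and at -2.57, -2.89 and -1.21 in flp-17oe egl-6(lof) against flp-17oe. C07G3.8 (chromosome V, 3498103 to 3502138), next to ugt-64, had 0.0617 CPM in N2, 0.363 in flp-17(lof), 0.211 in egl-6(lof), 0.0718 in flp-17oe and 0.253 in flp-17oe egl-6(lof). No explanation for the chromosome I genes was tested here.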
